A study of Mus musculus with 6 samples.

How the data were processed

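RNA from mouse immortalised bone-marrow-derived macrophages was measured in 6 libraries, 1 for each combination of 3 genotypes (wild type, IRF3-/-, IRF7-/-) with mock treatment or infection by Toxoplasma gondii ME49. Per the labels' protocols, cells were grown in DMEM with serum, glutamine and antibiotics, total RNA was isolated with an RNeasy Mini kit, and libraries followed a standard Illumina protocol. Strandedness, the time after infection and the dose of parasites are not given in the sources used here. Per the submitters' processing notes, reads were processed with CASAVA 1.8 and aligned with HISAT2 to GRCm38/mm10. The aligner version, the tool that counted reads, the annotation release and the size-factor method are not given in the sources used here.

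The deposited values are a normalized signal per gene, made by the authors by dividing whole read numbers by 1 factor per library. The factor is not written in the headers and was recovered from the values: in each library 100% of the values were whole multiples of 1 step, at a tolerance of 0.001 reads. The recovered factors were 0.9165 and 0.7672 (wild type, mock and infected), 1.0418 and 0.8431 (IRF3-/-) and 1.3341 and 1.2803 (IRF7-/-), and they equal median-of-ratios factors computed from the recovered reads. Each library had 18152 genes, and the lowest total over the 6 libraries was 10 reads, reached by 252 genes. Symbols, biotypes, coordinates and exon lengths came from GENCODE mouse release 21 on GRCm38, which covered 18114 of the genes, and 45 had no symbol. Gene-level values do not show isoforms or a deleted exon.

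The depth was 16270600 and 12211307 reads (wild type, mock and infected), 18107992 and 17253510 (IRF3-/-) and 21245193 and 21454698 (IRF7-/-), with 16850 to 17786 genes above 0 in a library. A single read corresponded to a value of 0.75 to 1.303. The precision of a ratio was given as a 95% conditional binomial (Clopper-Pearson) interval on the recovered reads. This interval covers counting error only, not differences between dishes or cell lines, and it is too narrow where reads are PCR copies, since no molecular barcodes are described. Where 1 library had 0 reads, the ratio was given as at least the value against a floor of 3 reads.

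The design was written before the data were examined and assumed that the values could be counts. The values turned out to be normalized, so the branch written for normalized values was used for the main results. The main scale was the log2 of the deposited value plus 1. A gene was measured in a pair of libraries when its value was at least 1 in at least 1 of them, and it was called higher or lower when the ratio was at least 2-fold and the counting interval excluded 1. The interval requirement was added after the unit was known. There are no p-values for pairs, because each holds 1 library against 1. A response difference was the log2 infection ratio in a mutant less that in wild type. It was counted when at least 2-fold in a gene with a value of at least 1 in any compared library, without a counting interval. The genotypes share the wild-type libraries, so comparisons of the mutants with wild type are not independent of each other.

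The additive model, limma-trend on the same log2 values, estimated infection averaged over the 3 genotypes, with genotype as covariate, and each mutant against wild type averaged over both infection states. It tested 17997 genes with a value of at least 1 in at least 3 libraries. It had 2 residual degrees of freedom and a median prior of 14.77, so its errors rest on the assumption that a genotype acts alike in both infection states, and genes with an interaction inflate the error. P-values were adjusted by Benjamini and Hochberg over all tested genes, and genes below 0.05 were called. For gene lists a count with the adjustment over the list alone was added, and fry tested each list for movement in 1 direction and in either direction. Tested on simulated data for the infection comparison, the model recovered 27 of 100 genes changed 2-fold and 97 of 100 changed 4-fold among 17876 genes, with 2 false calls.

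As alternatives, edgeR, limma-voom and DESeq2 were run on the recovered reads. EdgeR called 247 genes higher and 185 lower for infection, 85 and 392 for IRF3-/- and 58 and 122 for IRF7-/- of 13410 tested. Other alternatives were quantile normalization, scaling by library total, TMM, pseudocounts of 0.1 and 5, minimum values of 0, 5 and 50, a model without the covariate, limma without trend, no filter, and leaving out each library in turn. A length correction was also tried, in which the trend of log2 value on log2 exon length, less its mean over libraries, was fitted per library by lowess on protein-coding genes with a mean of at least 50 and subtracted.

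There were 36 gene lists, fixed before the data were examined. A list's median log2 ratio was placed among the medians of 10000 random lists matched on expression in 20 bins, as a description and not a test. One list, of type I interferon genes, had no measured member and is not analysed here, and Ifnb1, Il12b and Mx1 are not analysed here either.

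Genes were named by a rule set before the data were examined. Irf3 and Irf7 came first. The 10 largest changes in each direction were named for infection in each genotype, for mock genotype comparisons and for the additive model, and 5 in each direction for infected genotype comparisons and response differences. Pairs were ranked by the log2 ratio of values plus 1, and pair genes needed a value of at least 5 in the higher library, and predicted genes, numbered clones, pseudogenes and unnamed genes were passed over. Up to 4 members with the largest changes were named for a list, and 12 infection genes chosen in advance were reported where measured. Genes named outside these rules were chosen after their values were seen. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.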

Results

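Immortalised bone-marrow-derived macrophages from C57BL/6 mice, either wild type or labelled IRF3-/- or IRF7-/-, were sequenced without infection (mock) or after infection with the type II Toxoplasma gondii strain ME49. There was 1 library for each of the 6 groups, so every ratio between 2 libraries compares those libraries, not the conditions. The values covered 18152 mouse genes, of which 12831 were protein-coding and 15413 were above 0 in all 6 libraries. The libraries held 12211307 to 21454698 reads in these genes. Fth1, which encodes the ferritin heavy chain, took 4.29% of the reads in the mock wild-type library and 1.57% in the infected IRF7-/- library, and protein-coding genes took 93.495% to 96.752% of the reads in each library.

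Irf7 and Irf3 encode the transcription factors named in the genotypes, and their own mRNAs behaved differently. Irf7 (ENSMUSG00000025498, chromosome 7, 141262706-141266481, GRCm38) fell in the libraries labelled IRF7-/-, with a log2 fold change of -2.16 and an adjusted p of 0.0167 over both infection states. Its values were 160.4 and 138 in the mock and infected wild-type libraries, 95 and 148 in those labelled IRF3-/-, and 23.2 and 45.3 in those labelled IRF7-/-, so a part of the signal remained. Irf3 (ENSMUSG00000003184, chromosome 7, 44997648-45002848) had values of 631, 557, 524, 574, 644 and 693 in the same order. In the libraries labelled IRF3-/-, Irf3 mRNA was therefore close to wild type, at a ratio of 0.831 (95% counting interval 0.738 to 0.936) without infection and 1.03 (0.904 to 1.18) with infection, and the fitted log2 fold change was -0.11 with an adjusted p of 0.948. Reads summed over a whole gene do not show whether the transcript was intact, and the genotype was taken from the labels.

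Infection was accompanied by higher mRNA of many genes for DNA replication and mitosis and of some genes for sterol synthesis and the response to low oxygen. Some immediate early genes and several chemokines had lower mRNA. Fosb, an AP-1 subunit, and Dusp1, a phosphatase that switches off MAP kinases, were among the genes that fell most, and Adm, which encodes adrenomedullin, rose most. Interferon-stimulated genes did not move as a group. These statements rest on a fit that averaged infection over the 3 genotypes, in which 327 genes rose and 257 fell of 17997 tested. Each of the 584 moved the same way in all 3 genotypes. The fit favours such genes, because its error comes from differences between the genotypes, so this agreement is not separate support. The genes with the largest rises were Adm (ENSMUSG00000030790, chromosome 7, 110627661-110629820; log2 3.27, SE 0.34, adjusted p 8.23e-05), Tgfbi (2.99), the chemokine gene Ccl22 (2.73), Gbp3 (2.67), Mir3091 (2.66), the histone genes Hist1h2ap (2.64) and Hist1h2ao (2.63), the lectin receptor gene Clec4a2 (ENSMUSG00000030148; 2.61), Smad6 (2.56) and Map2k6 (2.55). The largest falls were of Fosb (ENSMUSG00000003545, chromosome 7, 19302696-19310051; -6.61, SE 0.43, adjusted p 4.75e-07), Cxcl2 (ENSMUSG00000058427; -4.42), Muc6 (-3.84), Sh2d6 (-3.83), Avil (-3.75), Ldhd (-3.63), Hid1 (-3.57), Ccl7 (-3.52), Dusp1 (ENSMUSG00000024190; -3.44, SE 0.26) and Dok7 (-3.33). Adm went from 155 to 714 in wild type, from 46.1 to 670.1 in IRF3-/- and from 50.2 to 697 in IRF7-/-, and Fosb from 751 to 3.91, from 567 to 16.6 and from 2695 to 13.3. Nos2, which encodes the inducible nitric oxide synthase, rose (1.47, adjusted p 0.0226). Arg1 at 1.31 and Tnf at -0.82 did not pass, with adjusted p of 0.0648 and 0.133.

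Among gene groups in the same fit, genes of S phase and replication rose in 23 of 32, with 31 when the adjustment covered the list alone. Tk1 (2.36), Uhrf1 (2.23), Ccne2 (2.22) and Rrm2 (1.92) were the largest. Of the mitosis genes 18 of 30 rose (27 over the list alone), led by Aurkb and Plk1 (each 1.94), Kif20a (1.93) and Birc5 (1.75). Hypoxia-response genes rose in 10 of 19 (10 over the list alone), among them Bnip3 (2.28), Egln1 (2.23) and Ddit4 (2.07), and glycolysis genes in 5 of 20 with 1 fall (12 and 2), Ldha at 1.75, Pfkl at 1.72 and Tpi1 at 1.46. Cholesterol synthesis genes rose in 9 of 23 (18), with Stard4 and Fdps at 1.8 and Idi1 at 1.72. Immediate early and ERK-response genes fell in 10 of 27 (16), including Fos (-2.57) and Dusp4 (-1.61). Of 12 chemokines 5 fell and 1 rose, the same over the list alone, with Ccl3 at -2.20. Of 25 inflammatory cytokines and effectors 5 fell and 2 rose (8 and 3), with Lcn2 at -2.52, Lif at -2.50 and Csf3 at -2.26. Integrated stress response genes fell in 4 of 21 (8, with 2 rises), Ppp1r15a at -2.38, Gdf15 at -2.35 and Ddit3 at -1.90. Plk2 (-2.33) and Btg2 (-1.60) were among 4 of 17 p53 targets that fell (6, with 1 rise), and Sqstm1 (-2.13) and Optn (-1.41) among 3 of 19 autophagy genes (6). No interferon-stimulated gene of 42 passed in limma-trend, where 2 had an unadjusted p below 0.05, and edgeR, voom and DESeq2 also called 0, with 2, 3 and 2 unadjusted. As whole sets, tested with fry, hypoxia, glycolysis and immediate early genes each had an adjusted p of 0.152 for movement in 1 direction and 0.047, 0.0296 and 0.0291 for movement in either direction, and S phase had 0.152 and 0.0396. Mitosis genes had 0.156 and 0.0709, cholesterol synthesis genes 0.156 and 0.0634, chemokines 0.304 and 0.101 and interferon-stimulated genes 0.616 and 0.189, and inflammatory genes, integrated stress response genes and p53 targets had 0.304 in 1 direction and 0.0295, 0.0291 and 0.0148 in either, so no list passed in 1 direction. Fry does not compare a set with other genes. Without the mock IRF7-/- library the S phase count was 8, mitosis 9, hypoxia 6, cholesterol synthesis 6, glycolysis 1, immediate early 5 and p53 targets 1, and without the infected IRF7-/- library they were 8, 10, 6, 7, 1, 6 and 1. Without any one of the other 4 libraries 8 glycolysis genes rose, and without either library labelled IRF3-/- 15 immediate early and 9 inflammatory genes fell. With limma without trend the counts of S phase, mitosis, hypoxia, cholesterol synthesis, glycolysis, immediate early, chemokine and inflammatory genes were all 0, with 29 S phase, 23 mitosis and 15 cholesterol synthesis genes higher and 12 immediate early genes lower at an unadjusted p below 0.05. Without the genotype in the fit 1 hypoxia and 2 immediate early genes remained, and 0 of S phase, mitosis and cholesterol synthesis.

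The count of genes depended on the libraries used. Leaving out the mock IRF7-/- library gave 117 genes higher and 99 lower, and leaving out the infected IRF7-/- library gave 117 and 107. Without the mock or infected wild-type library 548 and 542 were higher, with 382 lower without the infected one, and without the mock or infected library labelled IRF3-/- 758 and 738 were higher and 645 and 670 lower. Of the 584 genes, 484 also passed after quantile normalization, 548 with the length trend removed, 535 in DESeq2 and 428 in edgeR. With limma without trend 0 of the 584 passed, with the genotype left out of the fit 5 passed, and 3255 of the 17997 genes had an unadjusted p below 0.05.

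In wild-type macrophages, most of the inflammatory and chemokine genes measured had lower mRNA in the infected library than in the mock one, and most sterol synthesis genes and some cell division genes had higher mRNA. Cxcl2, a chemokine that attracts neutrophils, had a value of 224 against 12148 in the mock library, and Ccl7 566 against 17686. Il6 was 40.4 against 295, while the monocyte chemokine receptor gene Cx3cr1 was 199 against 13.1. Nos2 and Arg1, which compete for arginine, were both higher. The mock wild-type library is also the reference for both mock genotype comparisons, so a departure of it alone would appear in all of them. Against it, the mock IRF3-/- and IRF7-/- libraries had medians of -0.539 and -1.233 for inflammatory genes and -1.327 and -1.468 for chemokines. Mitosis genes, by contrast, were at -0.908 and -0.213. Pattern recognition genes were at 0.441 and 0.577, and cholesterol synthesis genes were split, at -0.226 and 1.097. Xirp1 had a value of 1.091 in mock wild type against 68.15 in mock IRF3-/- and 70.46 in mock IRF7-/-. Cx3cr1 was at 361.9 in mock IRF3-/-. For the inflammatory, chemokine and pattern recognition genes, and for Xirp1 and Cx3cr1, such a departure cannot be told apart from infection in this pair. Of 18048 genes measured, 1121 were at least 2-fold higher and 1305 at least 2-fold lower with a counting interval that excluded 1. Genes of a pair were ranked by the log2 ratio of values plus 1, so the rank of genes with few or 0 reads depends on that pseudocount and is not the order of the folds. The largest higher genes on this scale were Xirp1 (41.8-fold, interval 7.03 to 1700), Tgfbi (38.2-fold), Ccl22 (28.7-fold), Cx3cr1 (15.2-fold, 8.47 to 30.1), Phf11b (at least 6.37-fold), F13a1 (at least 4.38-fold), Gbp3 (at least 3.98-fold) and Zdhhc23, Pigz and Cd101 (each at least 3.58-fold). The largest lower genes on the same scale were Fosb (192-fold, 65.4 to 933), Cxcl2 (54.2-fold, 46.6 to 63.4), Rpph1 (33.9-fold), Rn7sk (33.6-fold), Ccl7 (31.3-fold), Il33 (at least 13.4-fold), U90926 (at least 6.98-fold), Erp27 (at least 5.3-fold), Krt23 (at least 5.02-fold) and Kif27 (at least 4.46-fold). Nos2 was 2.22-fold higher (2.14 to 2.31), Arg1 3.54-fold higher (2.22 to 5.81), Tnf 3-fold lower (2.82 to 3.2), Cxcl10 5.55-fold lower (2.62 to 13.5), Isg15 2.75-fold lower (1.14 to 7.59) and Gbp2 9.56-fold higher (1.28 to 424). Ccl5, Ifit1 and Irgm1 were at ratios of 1.25, 0.896 and 1.16, and Myc was 1.39-fold lower.

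Among the groups in this wild-type pair, cholesterol synthesis genes were higher in 17, lower in 0 and neither in 6 of 23 (median log2 1.32; Stard4 4.7-fold, Idi1 4.44-fold, Lss 3.5-fold). S phase genes were higher in 14 and neither in 18 of 32 (0.93; Uhrf1 5.48-fold, Tk1 4.46-fold), and mitosis genes higher in 9 and neither in 21 of 30 (0.71; Kif20a 4.99-fold, Plk1 3.29-fold). Hypoxia genes were higher in 6 and neither in 13 of 19 (0.71; Egln1 3.72-fold, Pdk1 3.51-fold), and pattern recognition genes higher in 6 and neither in 20 of 26 (0.50; Tlr8 10.5-fold, Nlrp1b 6.67-fold). Immediate early genes were lower in 18 and neither in 9 of 27 (-1.51; Phlda1 15.2-fold, Dusp1 8.81-fold, Hbegf 7.79-fold lower). Inflammatory genes were higher in 3, lower in 17 and neither in 5 of 25 (-1.45; Lcn2 11.1-fold, Il10 10.2-fold lower), and chemokines higher in 1, lower in 7 and neither in 4 of 12 (-1.73; Ccl4 11.8-fold lower). Interferon-stimulated genes were mixed, higher in 5, lower in 3 and neither in 34 of 42 (0.20), among them Mx2 3.98-fold and Samd9l 2.67-fold higher. Ribosomal protein genes were neither in 30 of 30 (-0.64), and histones lower in 3 and neither in 11 of 14 (-0.78). Beside all these groups, long genes were higher than short ones in this pair, with a median of -0.28 in the shortest eighth and 0.19 in the longest (Spearman 0.211), ribosomal RNA took 0.2% of the reads against 0.648%, and Rn7sk went from 350.2 to 10.4. Per library total instead of the deposited scaling, all genes shifted by a median of 0.131 log2 and 60.5% of the called genes were higher, against 46.2%.

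In macrophages labelled IRF3-/-, infection was accompanied by higher mRNA of nearly the whole mitotic programme. Ccnb2 and Birc5, which act in entry into mitosis and in chromosome segregation, were more than 8-fold higher. Many genes of oxidative phosphorylation and replication-dependent histones were higher as well. Trib3 and Atf5 of the integrated stress response were lower. Of 17578 genes 1990 were higher and 1713 lower. The largest higher genes by log2 of the value plus 1 were Cav1 (63-fold, 10.8 to 2540), the histone genes Hist1h3i (48.2-fold), Hist1h4f (45.7-fold), Hist1h2af (43.2-fold), Hist1h2bb (33.4-fold), Hist1h2ag (25.1-fold), Hist1h2ao (16.1-fold) and Hist1h4j (at least 9.06-fold), the antisense gene Rab26os (44.5-fold) and Map2k6 (at least 7.83-fold). Reads shared among related histone genes were not checked, and strandedness, which matters for Rab26os, was not stated. The largest lower genes on the same scale were Avil (68.0-fold, 11.9 to 2720), Fosb (34.2-fold, 20.2 to 62.9), Ccl7 (29.0-fold), Cxcl2 (22.9-fold), Wdr66 (at least 15.4-fold), Npas1 (at least 8.9-fold), Dok7 (at least 8.09-fold), Gvin1 (at least 6.2-fold), Tns2 (at least 5.93-fold) and Ldhd (at least 5.67-fold). Nos2 was 1.56-fold higher, Arg1 1.4-fold (0.88 to 2.24) and Cxcl10 1.85-fold (0.212 to 22.2), Tnf 1.39-fold lower, and Irgm1 and Myc were at 1.06 and 0.999. Isg15, Ifit1 and Trim30a had 0 reads in both libraries.

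In the groups of this pair, mitosis genes were higher in 28 and neither in 2 of 30 (1.85; Ccnb2 8.52-fold, Birc5 8.42-fold, Plk1 7.02-fold), and S phase genes higher in 26 and neither in 6 of 32 (1.81; Tk1 9.76-fold, Ccne2 6.23-fold). Cholesterol synthesis genes were higher in 17 and neither in 6 of 23 (1.22; Fdps 6.77-fold, Pmvk 4.6-fold), hypoxia genes higher in 11 and neither in 7 of 18 (1.43; Adm 14.5-fold, Ddit4 8.47-fold) and glycolysis genes higher in 11 and neither in 9 of 20 (1.05). Immediate early genes were lower in 8 and neither in 19 of 27 (-0.55; Dusp1 10.2-fold, Fos 5.08-fold lower), and integrated stress response genes lower in 9 and neither in 12 of 21 (-0.90; Trib3 6.74-fold, Atf5 5.86-fold lower). Pattern recognition genes were lower in 4 and neither in 22 of 26 (-0.51; Tlr7 2.73-fold, Tlr8 2.36-fold lower). Interferon-stimulated genes were higher in 2, lower in 4 and neither in 27 of 33 (-0.10). There were 3 groups that moved together with the differences in length trend, ribosomal RNA share and small RNAs given below, whose cause was not tested. Oxidative phosphorylation genes were higher in 16 and neither in 12 of 28 (1.13; Cox7a2 4.64-fold, Cox6c 3.92-fold), ribosomal protein genes higher in 9 and neither in 21 of 30 (0.94; Rpl27 2.58-fold), and histones higher in 10 and neither in 4 of 14 (1.86). With the length trend removed the ribosomal protein median was 0.31 and the histone median 0.73. Beside these groups, short genes were higher than long ones in this pair, with a median of 0.78 in the shortest eighth and -0.51 in the longest (Spearman -0.449), ribosomal RNA took 1.883% of the reads against 0.444%, and the small RNA Rn7sk went from 209 to 1356 and Rpph1 from 60.5 to 467. Mitochondrially encoded genes had a median of 0.27 that turned to -1.06 with the length trend removed. Per library total all genes shifted by -0.259 log2 and 32.8% of the called genes were higher, and with the length trend removed the shift was -0.240 and the share 41.6%, against 53.7%.

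**Figure D1:**
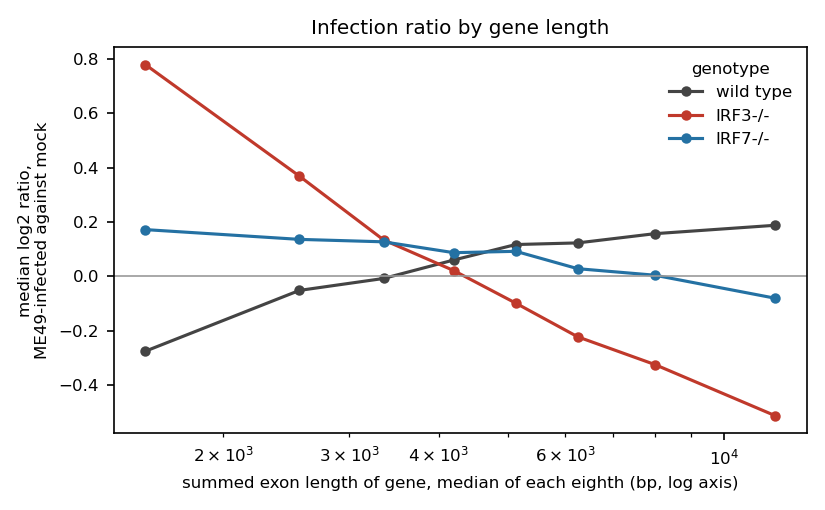
Median log2 ratio of infected over mock libraries in each eighth of protein-coding genes by exon length, for the 3 genotypes. The slope was downward in libraries labelled IRF3-/- (0.78 to -0.51) and upward in wild type (-0.28 to 0.19).

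In IRF7-/- macrophages, infection was accompanied by higher mRNA of many cell-cycle and hypoxia genes and of some ribosome biogenesis and interferon-stimulated genes. Adm and P4ha2, targets of the low-oxygen response, were more than 13-fold higher. Calr and Pdia4, which fold proteins in the endoplasmic reticulum, were also higher. Of 17803 genes 933 were higher and 1619 lower. By log2 of the value plus 1 the largest higher genes were Rpph1 (35.9-fold), Hist1h3c (19.8-fold), Nodal (18.2-fold), Dmpk (17.3-fold, 10.6 to 30.1), P4ha2 (17.1-fold), Hist1h2ap (16.7-fold), Ms4a6c (14.7-fold), Adm (13.9-fold), Atp7b (at least 5.56-fold) and Aebp1 (at least 4.52-fold). The largest lower genes on the same scale were Fosb (203-fold, 127 to 349), Muc6 (50.9-fold), Sptbn5 (37.4-fold), Hid1 (31.7-fold), Mmp28 (25.9-fold), Sh2d6 (21.3-fold), Mas1 (16.1-fold), Dusp1 (14.3-fold) and Tinagl1 and Ldhd (each at least 6.4-fold). Nos2 was 6.13-fold higher (5.8 to 6.49), Arg1 3.22-fold (2.74 to 3.8), Gbp2 16.7-fold (4.25 to 144), Ifit1 4.07-fold (2.07 to 8.76), Cxcl10 2.03-fold (1.16 to 3.68), Isg15 1.85-fold (1.24 to 2.8) and Myc 2.28-fold, while Tnf was 1.32-fold lower and Irgm1 was at 1.16. S phase genes were higher in 23 and neither in 9 of 32 (1.39; Ccne2 6.17-fold, Cdc6 4.08-fold), mitosis genes higher in 17 and neither in 13 of 30 (1.11) and hypoxia genes higher in 11 and neither in 7 of 18 (1.41; Bnip3 5.48-fold). Myc targets and ribosome biogenesis genes were higher in 12 and neither in 13 of 25 (0.95; Nolc1 3.06-fold, Srm 2.7-fold), and unfolded protein response genes higher in 4 and neither in 16 of 20 (0.62; Calr 2.14-fold, Pdia4 2.11-fold). Interferon-stimulated genes were higher in 5 and neither in 37 of 42 (0.28, above 99.84% of random lists of like expression; Rtp4 5.64-fold, Cmpk2 3.79-fold). Immediate early genes were lower in 9 and neither in 17 of 26 (-0.62), and inflammatory genes higher in 6, lower in 7 and neither in 12 of 25 (-0.18). Histones were higher in 6 and neither in 8 of 14 (1.31, or 0.82 with 0-read genes at their bound), beside Rn7sk at 162 against 18.0 and a small downward length trend (Spearman -0.127). Per library total all genes shifted by -0.119 log2, and with the length trend removed by -0.156.

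The 3 responses shared a common part. Higher in all 3 pairs were 149 genes and lower 196, and these pairs have no library in common. Tk1 went from 297 to 1324 in wild type, from 185 to 1809 in IRF3-/- and from 672 to 2086 in IRF7-/-, and Bnip3 from 2346 to 7292, from 1474 to 9895 and from 1166 to 6395. Wild type and IRF7-/- shared 282 higher and 452 lower genes, against 58.3 and 115.0 for independent lists, wild type and IRF3-/- shared 287 and 342 against 123.2 and 120.1, and IRF3-/- and IRF7-/- shared 391 and 448 against 102.1 and 151.4. Over 10724 genes the log2 ratios had a Pearson correlation of 0.528 between wild type and IRF7-/-. It was 0.488 between IRF3-/- and IRF7-/- and 0.202 between wild type and IRF3-/-. With the length trend removed the values were 0.563, 0.499 and 0.335. Spearman values in the same order were 0.489, 0.444 and 0.105, and 0.533, 0.447 and 0.252 with the trend removed.

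The responses also differed in size for single genes, with 1 library per group and no test of the difference. Il6 was lower with infection in wild type and higher in IRF7-/-, from 295 to 40.4 and from 3 to 33.6. Il33 had a value of 52.4 in the mock wild-type library and 0 after infection, and 0 in both libraries labelled IRF3-/-. Between IRF3-/- and wild type the response differed at least 2-fold for 7392 of 18135 genes, 3825 higher and 3567 lower. These were 2595 and 5285 per library total, 2100 and 4612 with the length trend removed, and 3717 and 3519 after quantile normalization. Between IRF7-/- and wild type it differed at least 2-fold for 4710 of 18143 genes, 2077 higher and 2633 lower. These were 1547 and 3414, 1426 and 3283, and 2418 and 2344 under the same settings. No counting interval was applied to these differences, so genes with few reads are included. With a minimum value of 50, 3560 genes remained for IRF3-/- and 1308 for IRF7-/-. Among the 5 largest differences of log2 ratios each way, those with reads in all 4 libraries were Rn7sk (7.63) and Rpph1 (7.56) for IRF3-/-, and Rpph1 (9.09), Rn7sk (8.04), Il6 (5.95) and Unc5a (-4.84) for IRF7-/-. The others had 0 reads in at least 1 library, so their size and rank depend on the pseudocount. For IRF3-/- these were Hist1h4f, Il33 and Cnih2 on the higher side and Slc16a8, C1qa, Npas1, Glis3 and Edaradd on the lower side. For IRF7-/- they were Tcf7 and Pnoc, and Paqr5, Vmn2r1, Ttll13 and Mir1942. As groups, mitosis genes had a median difference of 1.06 and S phase genes 0.82 for IRF3-/-, and interferon-stimulated genes -0.44. Histones at 2.643, ribosomal protein genes at 1.605 and oxidative phosphorylation genes at 1.211 differed more, beside the length trend. Against wild type, mitosis and S phase genes in IRF3-/- were at -0.908 and -0.925 in mock libraries and 0.168 and -0.214 in infected ones. Interferon-stimulated genes were at -0.394 in mock and -1.137 in infected libraries, with 0-read genes at their bound. For IRF7-/- chemokines had 1.25, inflammatory genes 0.98, unfolded protein response genes 0.89 and interferon-stimulated genes -0.02. Against wild type, chemokines in IRF7-/- were at -1.468 in mock and -0.145 in infected libraries. Inflammatory genes were at -1.233 and -0.29, and unfolded protein response genes at -0.598 and 0.254. Ribosomal protein genes in IRF3-/- were at -0.081 against wild type in mock and 1.549 in infected libraries. Histones there were at -0.475 and 2.759, and oxidative phosphorylation genes at -0.321 and 0.835. These groups and the interferon-stimulated genes of IRF3-/- differed from wild type more in infected than in mock libraries. The other groups compared this way differed more in mock libraries.

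**Figure D2:**
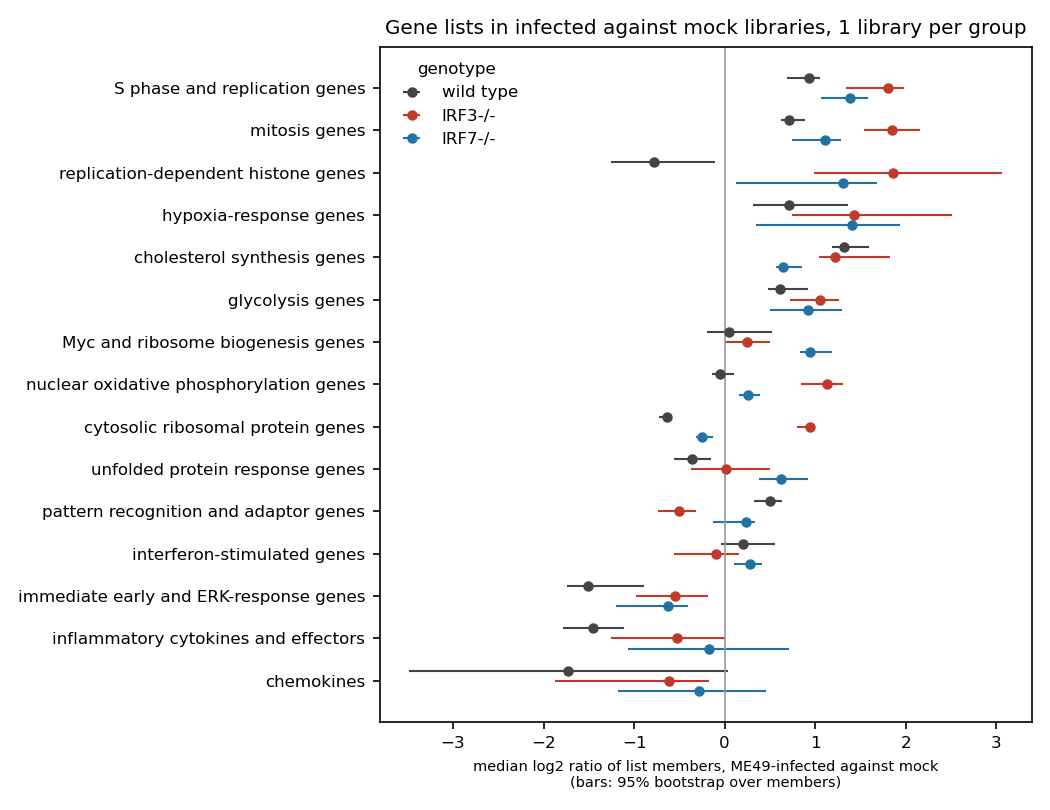
Median log2 ratio of infected over mock for 15 gene lists in the 3 genotypes, with 95% bootstrap ranges over list members. Mitosis genes were at 0.71 in wild type, 1.85 in IRF3-/- and 1.11 in IRF7-/-.

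In the libraries labelled IRF3-/-, several interferon-stimulated genes were low both without and with infection. Oasl1, which limits translation of Irf7, and Rsad2, which encodes the antiviral enzyme viperin, were well expressed in wild type and at or near 0 reads there. Of the interferon-stimulated genes at 50 or more in both wild-type libraries, 3 were at 4 or less in both libraries labelled IRF3-/-. Lgals3bp was lower, at 11.5 and 3.56 against 318 and 468, and Trim30a and the chemokine gene Ccl5, less expressed in wild type, were near 0. Isg15 and Ifit1 had 0 reads there but only 9.1 and 7.8 in the infected wild-type library. Genes outside the interferon response, such as the tetraspanin gene Tspan7 and the junction gene Cgnl1, were also near 0 there. Over both infection states 125 genes were higher and 559 lower than in wild type. All 684 had the same sign in both pairs, which the fit favours. The largest rises were of Ccdc148 (6.33, SE 0.68, adjusted p 1.03e-05), Acot4 (5.95), Tmtc2 (5.39), Lhfpl4 (4.61), Igsf9b (4.59), Mfsd7a (4.57), Irs2 (4.54), Ptger3 (4.53), Mamdc2 (4.44) and Ptprn (4.34). The largest falls were of Tspan7 (ENSMUSG00000058254; -9.58, SE 0.42, adjusted p 3.96e-10), Cgnl1 (ENSMUSG00000032232; -9.47), Oasl1 (ENSMUSG00000041827, chromosome 5, 114923240-114937915; -8.70, SE 0.46, adjusted p 3.88e-09), Ica1 (-8.68), Rras2 (-8.59), Acot1 (-8.45), Cd48 (-8.42), Gatm (-8.30), Sel1l3 (-8.28) and Tbxa2r (-8.12). Where a genotype had 0 reads, as for Oasl1, the size of the fitted value depends on the pseudocount, so these falls are not ranked. Of 42 interferon-stimulated genes 14 fell (18 over the list alone), including Rsad2 (ENSMUSG00000020641; -6.68), Lgals3bp (ENSMUSG00000033880; -5.68), Trim30a (ENSMUSG00000030921; -5.55), Isg15 (-4.02, adjusted p 0.00255) and Ifit1 (-3.21, adjusted p 0.0288). Ccl5 fell (-4.37, adjusted p 0.000469), Cxcl10 did not pass (-2.83, adjusted p 0.051), and Gbp6 (-3.67), Gbp9 (-3.55), Nlrc5 (-3.64), Il6 (-3.96) and Csf1 (-3.87) fell. Macrophage identity genes were split, 3 up and 3 down of 31 (5 and 5 over the list alone), with Cx3cr1 at 3.87, Marco at 2.72 and C1qb at -2.30. As a set the interferon-stimulated genes had a fry adjusted p of 0.105 for movement in 1 direction and 0.00994 for either direction, identity genes 0.496 and 0.00994, and inflammatory genes 0.613 and 0.0806. Without the mock library labelled IRF3-/- the counts were 810 higher and 1082 lower, without the infected one 314 genes were higher, and without the mock wild-type library 212 were higher. Without the infected wild-type library 4 identity genes were higher and 0 lower, and without the mock library labelled IRF3-/- 5 and 5. In DESeq2 588 of the 684 also passed, 476 in edgeR and 569 after quantile normalization, but 359 with limma without trend and 352 with infection left out of the fit. In these last 2 fits 10 and 11 interferon-stimulated genes fell, and 1 identity gene rose in each with 0 and 1 falls.

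**Figure D3:**
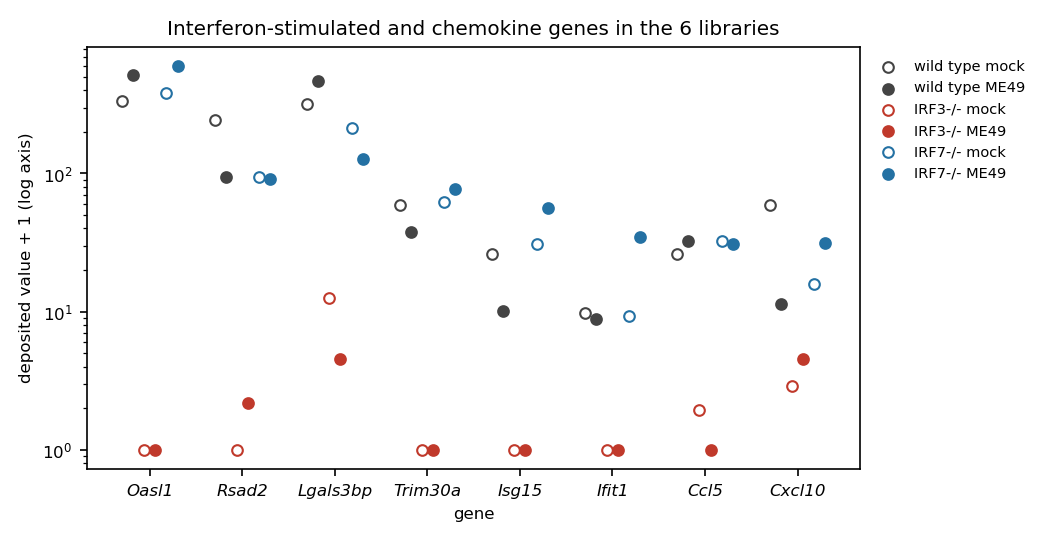
Values of 8 interferon-related genes in the 6 libraries, mock (open) and ME49 (filled). Oasl1 was at 333 and 517 in wild type, 0 and 0 in libraries labelled IRF3-/-, and 379 and 597 in IRF7-/-.

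Without infection, the library labelled IRF3-/- differed from wild type in several interferon-stimulated and cytokine genes. Irs2, an insulin signalling adaptor, and Cx3cr1 were higher, and the growth factor gene Csf1 was lower. Of 17990 genes 1086 were higher and 1837 lower. The largest higher genes by log2 of the value plus 1 were Tmtc2 (160-fold, 28.4 to 6360), Lhfpl4 (63.8-fold), Xirp1 (62.5-fold), Ccdc148 (56.3-fold), Acot4 (43.4-fold), Irs2 (39.0-fold, 22.1 to 76.0), Ptger3 (35.7-fold), Igsf9b (32.3-fold), Cx3cr1 (27.6-fold) and Arhgef19 (at least 10.3-fold). The largest lower genes on the same scale were Tspan7 (1540-fold, 275 to 60700), Cgnl1 (764-fold), Rras2 (at least 162-fold), Gbp8 (at least 158-fold), Ica1 (at least 156-fold), Oasl1 (at least 116-fold), Acot1 (at least 104-fold), Lrrc8b (at least 100-fold), Rsad2 (at least 84.1-fold) and Ppp1r3b (at least 77.7-fold). Cxcl10 was 30.1-fold lower (7.94 to 255), Ccl5 26.1-fold lower (4.25 to 1080), Isg15 at least 8.71-fold and Ifit1 at least 3.03-fold lower. Nos2 was 1.71-fold and Myc 1.45-fold lower, Tnf and Irgm1 were at 1.06 and 0.91, and Irf7 was at 0.592 (0.454 to 0.77). Interferon-stimulated genes were higher in 1, lower in 15 and neither in 25 of 41 (-0.82, or -0.39 with 0-read genes at their bound). Chemokines were higher in 2, lower in 8 and neither in 3 of 13 (-1.33), and inflammatory genes higher in 1, lower in 10 and neither in 14 of 25 (-0.54; Il6 13.3-fold, Csf1 10.8-fold lower). Hypoxia genes were lower in 8 and neither in 11 of 19 (-0.85), mitosis genes lower in 14 and neither in 16 of 30 (-0.91) and S phase genes lower in 12 and neither in 20 of 32, beside an upward length trend (Spearman 0.245).

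With infection, interferon-stimulated genes were again lower in the library labelled IRF3-/- than in wild type, and whether infection changed the difference was not tested. Lgals3bp was at 3.56 against 468 in wild type, and Oasl1 at 0 against 517. Guanylate-binding protein genes, which act on the parasite vacuole, were lower too, but Gbp8 among them was also at 0 in both IRF7-/- libraries. Of 17922 genes 1675 were higher and 1887 lower. Highest by log2 of the value plus 1 were Ccdc148 (249-fold, 44.4 to 9880), Rpph1 (179-fold), Rn7sk (130-fold, 65.8 to 302), Acot4 (at least 29.1-fold) and Hist1h4f (at least 11.2-fold). Lowest on the same scale were Cgnl1 (1840-fold, 330 to 72700), Tspan7 (at least 220-fold), Tbxa2r (at least 180-fold), Cd48 (at least 178-fold) and Gatm (at least 170-fold). Ccl5 was at least 8.79-fold lower, Gbp2 at least 2.93-fold, Isg15 at least 2.56-fold and Ifit1 at least 2.2-fold, and Cxcl10 was 2.93-fold lower (0.703 to 17.2). Nos2 was 2.43-fold lower, Arg1 1.94-fold lower and Tnf 2.28-fold higher, and Irf7 was at 1.07. Interferon-stimulated genes were higher in 1, lower in 26 and neither in 15 of 42 (-1.39, or -1.14 with 0-read genes at their bound; Lgals3bp 132-fold, 44.6 to 641, Rsad2 79.1-fold lower, 13.8 to 3170). Interferon-induced GTPase genes were higher in 1, lower in 7 and neither in 2 of 10 (-1.79, or -1.43; Gbp8 at least 31.5-fold, Gbp6 at least 4.4-fold lower), and reads shared among related Gbp genes were not checked. Ribosomal protein genes were higher in 29 and neither in 1 of 30 (1.55; Rps16 3.6-fold, Rps23 3.43-fold), histones higher in 9 and neither in 5 of 14 (2.76) and oxidative phosphorylation genes higher in 10 and neither in 18 of 28. Beside these 3 groups stood the downward length trend (0.71 in the shortest eighth, -0.48 in the longest, Spearman -0.453), the ribosomal RNA share of 1.883% against 0.2% and Rn7sk at 1356 against 10.4. The ribosomal protein median was 0.71 after quantile normalization and 0.99 with the length trend removed. Per library total all genes shifted by -0.369 log2 and 20.7% of the called genes were higher, and with the length trend removed by -0.205 with 33.0% higher, against 47.0%.

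In IRF7-/- macrophages, genes of the complement component C1q and the scavenger receptor gene Marco were much higher than in wild type in both infection states. C1qa, C1qb and C1qc together form the recognition molecule of the classical complement pathway. The early-response gene Egr1 and the growth factor gene Csf1 were lower, and so were several chemokines. Oasl1, Ccl5 and Trim30a, which were near absent in the libraries labelled IRF3-/-, were close to wild-type levels or above. Over both infection states 75 genes rose and 194 fell, all 269 with the same sign in both pairs, which the fit favours. Among genes that reached a value of 1 in at least 3 libraries, which leaves out genes seen in IRF7-/- alone such as Gpr37l1, the largest rises were of C1qa (ENSMUSG00000036887, chromosome 4, 136895917-136898803; 7.20, SE 0.92, adjusted p 0.000278), C1qc (ENSMUSG00000036896; 6.18), C1qb (ENSMUSG00000036905; 5.81), F13a1 (5.77), Tgfbi (5.21), Marco (ENSMUSG00000026390; 4.82, SE 0.35, adjusted p 5.27e-07), Nxpe5 (4.03), Mcemp1 (3.89), Lrg1 (3.81) and Mertk (3.73). The largest falls were of Tceal8 (-7.45), Lrp5 (-7.41), Ppic (-7.36), Dmwd (-7.31), Ddx3y (-7.09), Bdh1 (-6.98), Col4a1 (-6.77), Egr1 (-6.23, SE 0.45, adjusted p 5.3e-07), Fkbp9 (-6.18) and Pcp4l1 (-6.04). Some of these, such as Ddx3y, Bdh1 and Col4a1, had 0 reads in both IRF7-/- libraries, so the size of the fitted value depends on the pseudocount and these falls are not ranked. C1qb was at 1058 and 1889 against 13.1 and 44.3 in wild type, and Marco at 2599 and 5763 against 131 and 141. Macrophage identity genes rose in 11 of 31 (13 over the list alone), immediate early genes fell in 5 of 27 (9, with 2 rises; Spry2 -5.36, Hbegf -3.98, Etv4 -3.93), inflammatory genes in 4 of 25 (9; Csf1 -4.10) and chemokines in 3 of 12 (5; Cxcl2 -3.02). Arg1 rose (2.34, adjusted p 0.0106), as did the interferon-stimulated genes Ddx60 (3.13) and Parp14 (1.95), 2 of 42 (5 over the list alone). Without the mock IRF7-/- library 21 genes were higher and 89 lower, without the infected one 35 higher, without the mock wild-type library 42 higher, without the infected wild-type library 231 higher, and without the mock or infected library labelled IRF3-/- 370 and 378 higher and 497 and 512 lower. The identity count was 7 without either IRF7-/- library, the immediate early count 3 without the mock wild-type library, 8 without the infected one and 10 without either library labelled IRF3-/-, and the inflammatory count 2 without the mock wild-type or mock IRF7-/- library, 7 without the infected IRF7-/- library, and 10 without any of the other 3. In DESeq2 239 of the 269 also passed, 178 in edgeR and 248 after quantile normalization, but 34 with limma without trend and 63 with infection left out of the fit. In these last 2 fits the identity count was 3 and 6, the immediate early count 3 in each, and the inflammatory count 0 in each, with 7 and 6 lower at an unadjusted p below 0.05. In fry the identity genes had an adjusted p of 0.135 for movement in 1 direction (0.435 with the length trend removed) and 0.0743 for either, immediate early genes 0.412 and 0.0744, inflammatory genes 0.444 and 0.0744, and chemokines 0.444 and 0.266, so none of these sets passed.

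Without infection, IRF7-/- macrophages had higher mRNA of some macrophage identity genes and of most cholesterol synthesis and LXR target genes, and lower mRNA of several cytokines. Abca1, which exports cholesterol, and Mrc1, which encodes the mannose receptor, were higher, and Il6 and Cxcl2 were lower. Of 18066 genes 1196 were higher and 1422 lower. The largest higher genes by log2 of the value plus 1 were Tgfbi (154-fold, 27.3 to 6110), C1qc (126-fold, 49.2 to 465), C1qb (80.8-fold, 46.1 to 157), Xirp1 (64.6-fold), Gpr37l1 (at least 114-fold), C1qa (at least 84.0-fold), F13a1 (at least 55.6-fold), Phf11b (at least 9.39-fold), Nxpe5 (at least 8.24-fold) and Lrg1 (at least 8.02-fold). The largest lower genes on the same scale were Dmwd (576-fold, 103 to 22800), Serpinb1a (229-fold), Egr1 (151-fold, 64.3 to 467), Ppic (151-fold), Gbp8 (at least 202-fold), Tceal8 (at least 197-fold), Lrp5 (at least 77.1-fold), Ddx3y (at least 74.7-fold), Bdh1 (at least 47.1-fold) and Col4a1 (at least 44.6-fold). Irf7 was 6.9-fold lower (4.66 to 10.5), Nos2 4.39-fold, Cxcl10 3.86-fold, Myc 3.62-fold and Tnf 3-fold lower, Arg1 5.41-fold higher (3.56 to 8.57), and Irgm1, Isg15 and Ifit1 were at 1.37, 1.19 and 0.945. Macrophage identity genes were higher in 14 and neither in 17 of 31 (0.92; Cx3cr1 28.5-fold), cholesterol synthesis genes higher in 13, lower in 1 and neither in 9 of 23 (1.10), efflux and LXR targets higher in 7, lower in 1 and neither in 3 of 11 (1.33; Abca1 6.93-fold) and interferon-stimulated genes higher in 11, lower in 2 and neither in 29 of 42 (0.50). Inflammatory genes were higher in 1, lower in 13 and neither in 11 of 25 (-1.23; Il6 98.3-fold, Csf1 25.6-fold lower), chemokines lower in 6 and neither in 6 of 12 (-1.47; Cxcl2 21-fold lower), immediate early genes higher in 2, lower in 12 and neither in 13 of 27 (-0.69) and hypoxia genes higher in 1, lower in 12 and neither in 6 of 19 (-1.07). Ribosomal protein genes were neither in 30 of 30 (-0.75), beside an upward length trend (Spearman 0.301). Per library total all genes shifted by 0.139 log2 and 60.4% of the called genes were higher, against 45.7%.

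With infection, C1q and Marco were again higher in IRF7-/- than in wild type, and so were several interferon-stimulated genes. Isg15 was at 55.5 against 9.1 and Ifit1 at 33.6 against 7.8. Of 17856 genes 501 were higher and 1104 lower. The largest higher genes by log2 of the value plus 1 were Gpr37l1 (at least 127-fold), C1qa (90.6-fold, 38.7 to 280), C1qc (54.7-fold), C1qb (42.6-fold) and Marco (40.9-fold, 33.9 to 50), and the largest lower genes on the same scale Ppic (541-fold, 96.4 to 21400), Lrp5 (273-fold), Bdh1 (at least 63.4-fold), Col4a1 (at least 49.5-fold) and Gbp8 (at least 47.8-fold). Isg15 was 6.08-fold higher (2.8 to 15.7), Ifit1 4.29-fold (1.82 to 12.3), Arg1 4.93-fold, Cxcl10 2.92-fold (1.35 to 7.24) and Gbp2 2.4-fold, while Irf7 was 3.05-fold lower (2.19 to 4.28), Nos2 1.59-fold, Tnf 1.32-fold and Myc 1.14-fold lower. Interferon-stimulated genes were higher in 15, lower in 1 and neither in 26 of 42 (0.64; Oasl2 11.4-fold, Ddx60 7.39-fold, Rtp4 5.23-fold), and macrophage identity genes higher in 13 and neither in 18 of 31 (0.71). Inflammatory genes were higher in 3, lower in 3 and neither in 19 of 25 (-0.29), and immediate early genes lower in 6 and neither in 21 of 27 (-0.30). Histones were higher in 5 and neither in 9 of 14 (1.10), beside Rn7sk at 162 against 10.4.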

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

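All tests in this part were chosen after the result they examine had been seen. A gene group was singled out when its median log2 infection ratio was above the central 95% of random lists of like expression in 1 genotype and below it in another, which gave 6 differences, not necessarily the largest ones. In IRF3-/- less wild type, pattern recognition genes differed by -1.01, ribosomal protein genes by 1.58 and histones by 2.64. In IRF7-/- less wild type, unfolded protein response genes differed by 0.98 and histones by 2.09, and ribosomal protein genes differed by -1.19 between IRF7-/- and IRF3-/-. Each is a difference between single libraries, and none of these differences was tested.

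Ribosomal protein, oxidative phosphorylation and histone genes were higher with infection in libraries labelled IRF3-/- than in wild type, next to a trend that favoured short genes. For this check the length trend was fitted per library as a cubic curve, not by the lowess used elsewhere. The fit took 9768 protein-coding genes and left out ribosomal protein (also mitochondrial), oxidative phosphorylation and histone genes. A transcript-length trend did not account for all of the ribosomal protein difference, since a median of 0.993 remained of 1.605 after its removal, above the 0.564 reached by random lists. The scaling between libraries left 0.668 under quantile normalization, above 0.362 for random lists. Histones went from 2.643 to 1.423 and 2.554 under the same 2 corrections, above 0.39 and 0.816 for random lists, and oxidative phosphorylation genes from 1.211 to 0.565 and 1.012, where with the trend removed the lower bootstrap limit of 0.319 lay within the random range, so for these the trend may be enough. Neither correction was aimed at a library difference in small RNAs. Rn7sk went from 350.2 to 10.43 with infection in wild type and was at 1356 in the infected library labelled IRF3-/-. Whether the histone difference belongs with this change of Rn7sk was not tested. Whether the loss of IRF3 acted on the infection response could not be examined with 1 library per state.

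A set of genes was near 0 in both libraries of a mutant genotype and at 50 or more in both wild-type libraries, 60 genes for IRF3-/- and 18 for IRF7-/-. A chromosome 7 segment carried along with the Irf3 locus was not the source, as 3 of the 60 lay on chromosome 7 (5.0%, interval 1.0 to 13.9, against 7.4% of the background). The same 8 genes were at 4 or less in all 4 mutant libraries, Dclk2, Yes1, Gbp8, Fkbp9, Col4a1, Slitrk5, Lrp5 and Ankrd2, but both sets were chosen against the same wild-type libraries, so cell lines of separate origin cannot be told apart from other causes by this count. The deleted factor alone would leave Y-linked genes in place, yet Kdm5d, Uty and Ddx3y, all 3 of those examined, had no read in either IRF7-/- library, so at least a part of the genotype differences may belong to the cell line. A 4th Y-annotated gene, Gm47283, had 227 and 196 there and was set aside after this was seen, because it lies in the region shared with the X chromosome.

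The median of the mitosis genes was above 0 with infection in all 3 genotypes, with 9 of 30 genes called higher in wild type, 28 in IRF3-/- and 17 in IRF7-/-. A transcript-length trend was not the source, as the mitosis list stayed at percentile 100 in every genotype after its removal. Mouse fibroblast RNA carried over with the parasites, which are commonly grown in fibroblasts, left little trace in its markers. Their sum rose by at most 0.182% of the rise of the mitosis sum. Acta2, the most abundant marker, was at 88.6 in the infected wild-type library. The cells in which the parasites were grown are not described in the sources used here, and RNA from another species was not examined. Macrophages also express a part of these markers, and no sort to remove other cells is described. Handling that differed between mock and infected dishes could still contribute, because 10 immediate early genes fell in the same comparison, and this cannot be told apart from infection here.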

How the results depend on the processing

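No paired analysis was possible because the labels give no replicate numbers and there is 1 library per group, apart from the matching of mock and infected libraries by genotype that the additive model itself makes; the fit without that term is among the settings. No counting interval, TMM, length trend removed, minimum 50 and edgeR on recovered reads were settings chosen after the result was seen. A count was called moved when it changed more than 1.5-fold. A list median was called moved when it left the bootstrap range over its members, and a named pair when it left its counting interval. A named additive gene was called weaker when its adjusted p was not below 0.05. None of the genes called in the additive model changed sign in the fits in which they were tested. This says little about stability, because the genes were chosen on the same libraries. Library total and other pseudocounts were not run in that model, and edgeR and voom tested 555 of the 584, 575 of the 684 and 208 of the 269 called genes. Directions did turn elsewhere: mitochondrially encoded genes in IRF3-/- infection went from 0.27 to -1.06 with the length trend removed. With the same removal, response differences of IRF3-/- went from mostly higher (3825 and 3567) to mostly lower (2100 and 4612), and per library total to 2595 and 5285. Those of IRF7-/- went from mostly lower (2077 and 2633) to 2418 higher and 2344 lower after quantile normalization. Over the settings that kept all 6 libraries, for pair counts 126 stayed and 28 moved, for response differences 17 and 3, for additive counts 37 and 17, for list medians 508 and 52, for list members 114 and 39, for named pairs 662 and 58, and of the named additive genes 428 stayed and 64 were weaker. With 1 library left out, 13 additive counts stayed and 23 moved, 66 list members stayed and 36 moved, and 341 named additive genes stayed and 19 were weaker. DESeq2 size factors for pairs are the deposited factors themselves and could move nothing. They make up 14 of the pair counts, 2 of the response differences and 112 of the list medians that stayed. Dropping the minimum value moved no pair count or response difference either, because a gene below 1 in every compared library cannot reach 2-fold. Among pair counts, a minimum of 5 changed only those of IRF7-/- infection, to 923 higher and 1576 lower.

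Without the counting interval, genes higher numbered 1908 (wild type infection), 1783 (IRF3-/- mock), 2044 (IRF7-/- mock), 2569 (IRF3-/- infected) and 1284 (IRF7-/- infected), the last 4 against wild type. Genes lower numbered 2511, 2951 and 2534 for infection in wild type, IRF3-/- and IRF7-/-, 2764 for IRF3-/- mock, and 3230 and 2169 for IRF3-/- and IRF7-/- infected. With a minimum value of 50 fewer genes remained by construction. Genes higher were then 710 (wild type infection), 661 (IRF3-/- mock), 724 (IRF7-/- mock) and 242 (IRF7-/- infected), and genes lower 675, 953 and 534 for the 3 infections, 935 and 683 for the mock and 1036 and 354 for the infected comparisons of IRF3-/- and IRF7-/-. Response differences were 3560 for IRF3-/- and 1308 for IRF7-/-. Per library total, IRF3-/- infection had 1302 higher and 2671 lower, and IRF3-/- infected against wild type 843 and 3230. With the length trend removed these had 1137 and 886 higher, and 479 genes fell in the additive infection contrast. With a pseudocount of 5 the IRF7-/- response differences were 2801.

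In the additive model limma without trend gave 0 higher and 0 lower for infection, 46 and 353 for IRF3-/- and 4 and 30 for IRF7-/-. Without the covariate these were 1 and 4, 43 and 309, and 9 and 54. Without trend all infection list counts fell to 0, from 23 for S phase, 18 for mitosis, 10 for hypoxia, 9 for cholesterol synthesis and 10 for immediate early genes. DESeq2 gave 554 higher for infection. For IRF7-/- voom gave 128 lower, edgeR 122, and edgeR with DESeq2 size factors 125. The cause of these shifts was not tested. Leaving out each library in turn gave 117 to 758 higher and 99 to 670 lower for infection, 117 to 810 and 473 to 1082 for IRF3-/-, and 21 to 378 and 89 to 512 for IRF7-/-. Each such fit leaves an arm with a lone library that is assumed to vary like the others. For infection the genotype term fits that lone library exactly, so it adds nothing to the estimate. The infection fits therefore amount to leaving out each genotype in turn and are not separate checks of each library.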

Other observations

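The values in this part were looked at after the main results had been seen, and so were the tests. Clec4a2 mRNA was higher with infection in each genotype, from 29.5 to 291 in wild type, from 113 to 476 in IRF3-/- and from 283 to 1621 in IRF7-/-. Tgfbi went from 1.09 to 41.7, from 6.72 to 43.9 and from 168 to 719, so both genes were also higher in IRF7-/- cells before infection. The autophagy receptor gene Sqstm1 and the stress cytokine gene Gdf15 both fell with infection. Lgals3bp and Ifit2 differed within the group of interferon-stimulated genes in libraries labelled IRF3-/-. Lgals3bp was at 11.5 and 3.56 against 318 and 468 in wild type, and Ifit2 at 17.3 and 20.2 against 74.2 and 117. Egr1 was at 3.7 and 3.1 in IRF7-/- against 566 and 193 in wild type, while Fos was at 1304 against 726 in the infected libraries. Ddx3y was at 168 and 108 in wild type, 1617 and 1096 in IRF3-/- and 0 in both IRF7-/- libraries.

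Genes on chromosome 16, 339 in number, had a median log2 ratio of 0.27 in IRF7-/- against wild type without infection and 0.37 with infection (interquartile range 0.117 to 0.571). In IRF3-/- against wild type the same genes were at -0.26 and -0.33. Other chromosomes lay between -0.103 and 0.064 for mock IRF7-/- and between -0.144 and 0.196 for infected IRF3-/-.

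Among gene lists not described above, in the additive fit for infection, lysosome genes had 0 called of 29 by limma-trend (median -0.33; 7 lower with an unadjusted p below 0.05), 0 by voom and edgeR (9 and 8 unadjusted) and 4 by DESeq2 (10 unadjusted). Alternative activation genes had 2 falls of 12, Klf4 (-1.87) and Cd200r1 (-1.24), macrophage identity genes 1 rise and 1 fall of 31, Cx3cr1 (2.34) and Cebpa (-1.49), and NF-kB feedback genes 1 and 1 of 23, Tnip3 (1.18) and Cd40 (-1.60). Scd2 (1.46) and Scd1 (1.42) were the 2 rises among 11 cholesterol efflux and LXR genes, Srm (1.01) the only 1 of 25 Myc and ribosome biogenesis genes, and Gbp3 the only 1 of 9 GTPase genes. Osgin1 (-1.46) was the only fall of 20 oxidative stress genes, Ighm (1.47) the only rise of 5 lymphocyte markers and Vwf (-1.82) the only fall of 4 epithelial and endothelial markers.

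Several lists had 0 genes called by limma-trend. Pattern recognition genes had 3 of 26 with an unadjusted p below 0.05 (4 in voom, 3 in edgeR and 3 in DESeq2, which called 1), MHC class I genes 6 of 18 (6 in each other tool, 0 called), unfolded protein response genes 5 of 20 (5, 5 and 6, with 1 called by DESeq2) and heat shock genes 1 of 13 (1, 1 and 3, with 1 called by DESeq2). Nuclear oxidative phosphorylation genes had 4 of 28 (3, 2 and 4, 0 called), mitochondrially encoded genes 2 of 13 (1, 1 and 1, 0 called), histones 5 of 14 (2 and 3 of 9, then 5 of 14 with 1 called by DESeq2) and dendritic cell markers 2 of 9 (1, 1 and 1, 0 called). Ribosomal protein genes had 0 of 30 in all 4 tools (median 0.02), MHC class II genes 0 of 3 (-0.61) and erythroid markers 0 of 4 (-0.63), and granulocyte markers had 0 of 8 except for 1 in edgeR. Fibroblast markers had 0 of 6 in limma-trend and 0 of 7 in DESeq2.

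The number of genes called for infection was also compared with other splits of the 6 libraries. Of 10 splits the real one gave 584 genes and the highest other 0, which is 1 of 10 over all splits. Only some of the 10 part the libraries of all 3 genotypes as the real one does, and the rest part those of 1 genotype. In the other splits the infection difference also goes into the error, which makes calls there unlikely. The comparison therefore cannot decide the question, and 10 splits are too few to reach a share below 0.05.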
